A study of Scophthalmus maximus with 2 samples.

How the data were processed

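Droplet single-cell RNA sequencing was done on the posterior intestine of turbot that had been injected with 100 µl of PBS or of β-glucan at 1 mg/ml and infected by immersion for 10 min in 40 L of water at 17 °C, per the labels. Sampling was 3 days after infection. Cells were enriched on a discontinuous Percoll gradient before capture with the Chromium 3' v3.1 chemistry, per the labels' protocols. The deposited matrices hold raw UMI counts, which the authors made without any normalization, as whole numbers per gene and barcode. The labels name Cell Ranger and Seurat with no version. The lowest deposited barcode held 500 UMIs in each library. Of 21020 features, 15709 carry a symbol and 5311 do not, and 0 of the latter could be matched in the reference table, so those were used for clustering but not for lists or named genes.

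Barcodes with at least 200 detected genes and at most 20% mitochondrial UMIs were kept, using 13 mitochondrial genes. In the PBS library 2194 barcodes (30.9%) and in the β-glucan library 1860 (33.6%) were over the mitochondrial limit. Doublets were scored per library with an implementation of the Scrublet algorithm in double precision with exact neighbours, 2 simulated doublets per cell, and the highest scores were removed at 0.8% of cells per 1000 cells, which removed 192 and 107 cells. This implementation replaced that of scanpy after a first run, so that the results could be repeated exactly. The kept cells were 4701 and 3547, with 21078831 and 22171391 UMIs.

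Cells of both libraries were clustered together without integration in scanpy 1.11.5: totals scaled to 10000, log values, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9), with seed 1, which gave 23 clusters. Clusters were named from marker genes of 19 classes fixed before the data were examined. The scoring rule was set after the data were seen and after other forms of it had been tried, such as folds over all other cells. A marker counted as raised at a log2 fold of at least 1 over the median of the other clusters and in at least 5% of the cells, and a class needed 3 raised markers with a mean log2 fold of at least 1. A cluster with more markers of another class than of its own among its top 10 genes, leaving out genes seen in about the same share of every cluster, stayed unnamed.

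UMIs were summed per library and class, scaled to CPM by total UMIs, and compared as log2 ratios with a pseudocount of 1 CPM, for genes with at least 30 UMIs over both libraries. Classes needed 100 cells in both libraries. Shares have exact Clopper-Pearson intervals, a share of 0 is given with the limit of 3 counts over the number of cells, and ratios of sums or shares have conditional exact binomial intervals without a pseudocount, so that a rare gene's ratio can lie outside its interval. For 22 gene lists fixed before the data were examined, the median log2 ratio over members was given for lists with at least 5 measured members, with an interval from 1000 Poisson redraws and its percentile among 10000 random lists matched in 20 expression bins, as a description of these libraries. The matching rule took 15 names that belong to another gene than the listed one, and the 17 features under them were left out of lists that did not name them, a choice made after the data were seen. To compare depth-dependent shares, cells were thinned to 800 UMIs. Genes were named by a rule fixed beforehand: ranked by the interval bound nearest 0, the 10 highest and 10 lowest in T-like cells and over all cells and the 5 highest and lowest in other classes, where the class level was not below 0.5 of the level over all cells, together with every measured type 3 member in T-like cells and the described list members with the most UMIs. With 1 library per group no test, p-value or count of changed genes was made.

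Alternatives covered the cell filter, doublets, clustering resolution, ComBat integration, classes from single cells, the denominator, scaling (TMM from edgeR 4.0.16 in R 4.3.3, median of ratios, totals without the 50 top genes), the pseudocount, the UMI minimum, thinning and means over cells. On simulated libraries of the same depths, intervals held the true ratio for 95.7% of genes over all cells and 95.8% in T-like cells. The simulated sums were Poisson draws, the model behind the intervals, without differences between cells or fish. These rates therefore check the computation and say nothing on such differences in the real libraries. Genes changed 1.5-fold were found in 78.8% and 53.8% of cases, and 2-fold in 94.0% and 90.6%. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19 and matplotlib 3.10.9.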

Results

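Single cells from the posterior intestine of turbot (Scophthalmus maximus), a flatfish, were profiled by droplet RNA sequencing 3 days after immersion infection with Edwardsiella piscicida, a bacterium that infects fish. The labels give 2 groups of infected fish with 1 library each. One group had received an intraperitoneal injection of PBS and the other of β-glucan, a polysaccharide of fungal cell walls that innate immune receptors recognise. The PBS library held 27233027 UMIs in 7103 barcodes and the β-glucan library 26605572 UMIs in 5539 barcodes. After the cell filters 4701 and 3547 cells were kept, with medians of 1564 and 2321 UMIs per cell. With 1 library per group there is no replicate, so no test was possible, and every interval given is a 95% interval that covers counting error only. No library from uninfected fish is among the data. The files give no gene positions.

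The first question is whether the cells of the infected intestine differed in makeup between the β-glucan and the PBS library. T-like cells were the most abundant class, with 2206 cells (46.9%, 45.5 to 48.4) in the PBS library and 1458 cells (41.1%, 39.5 to 42.7) in the β-glucan library. Enterocyte-like cells, the absorptive epithelium, made up 31.6% (30.3 to 33.0) and 36.2% (34.6 to 37.8). Much of this difference lay in cluster 14, with 4 PBS cells (0.0851%) and 120 β-glucan cells (3.38%). Of the other enterocyte-like clusters, cluster 5 was higher in the β-glucan library (log2 ratio of shares 0.40) and cluster 11 lower (-0.68). The intervals of clusters 3 and 4 included 0. Erythroid-like cells were higher in the β-glucan library, at 4.68% (4.01 to 5.43) against 2.64% (2.20 to 3.14), and macrophage-like cells were lower, at 1.55% (1.17 to 2.01) against 2.25% (1.85 to 2.72). The intervals of the ratio between libraries included 0 on the log2 scale for B-like, goblet-like, enteroendocrine-like and tuft-like or ionocyte cells.

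Both directions for the large classes turned with the cell filter. With at least 500 genes and at most 10% mitochondrial UMIs the log2 ratio of shares, β-glucan over PBS, went from -0.19 to 0.21 for T-like cells and from 0.20 to -0.18 for enterocyte-like cells, while that of erythroid-like cells moved from 0.83 to 1.83. The T-like ratio also turned with classes taken from single cells (0.097). Among immune-like cells alone it was 0.0024, but that denominator is nearly all T-like, so the ratio could hardly leave 0. Beside the T-like cells it held 72 B-like and 106 macrophage-like cells of the PBS library and 60 and 55 of the β-glucan library. Cells had been enriched on a Percoll density gradient, and the libraries differed in depth, both of which can set such shares. Clusters left without a name by thresholds set after the data were seen held 7.40% of PBS and 8.09% of β-glucan cells. Among them was cluster 8, led by nkl.3, trac, tbx21 and il10, with 2.51% and 5.05%. It had 9 raised T markers, cd8a, cd8b and lck among them, at a mean log2 fold of 4.18. It stayed unnamed only because its top 10 genes held 2 markers of another class against 1 of T cells. Its own log2 ratio of shares was 1.01 (0.66 to 1.36). With it counted as T-like, the T-like share ratio became less negative. It stayed within its interval (-0.29 to -0.095), but near the upper bound. Clusters 15, 18, 19 and 23 held 2.04%, 1.17%, 1.32% and 0.362% of PBS cells and 0.705%, 1.13%, 0.902% and 0.310% of β-glucan cells. Cluster 15, with the tuft cell gene avil among its top 10 genes, had a log2 ratio of shares of -1.53 (-2.23 to -0.89). The intervals of clusters 18, 19 and 23 included 0.

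**Figure D1:**
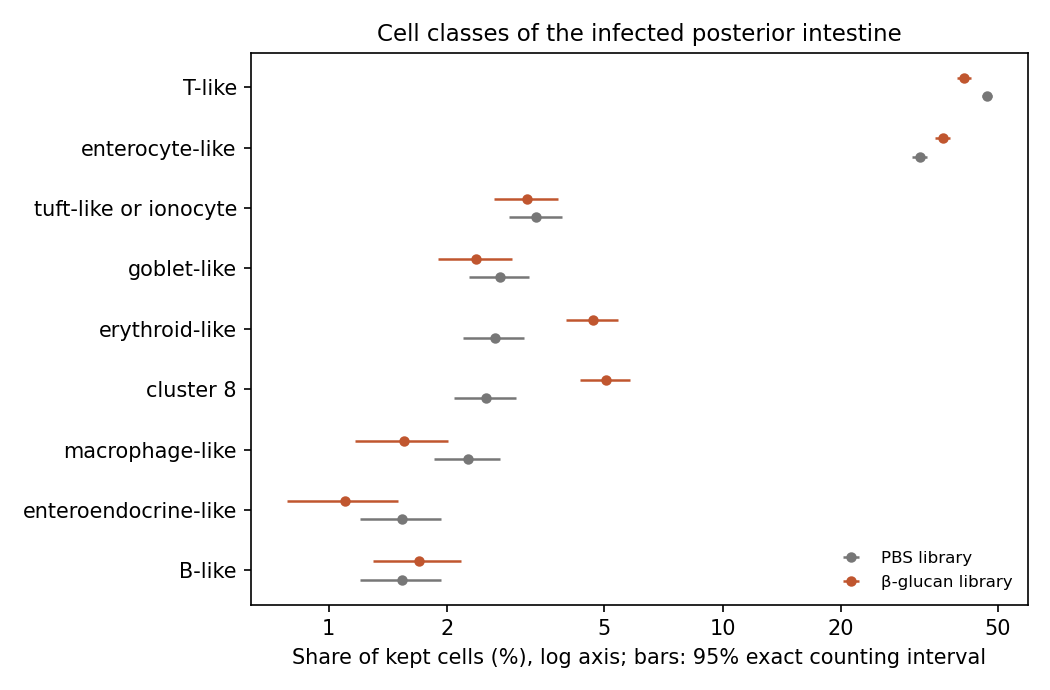
Share of kept cells in each class (percent, log axis) in the PBS library (grey) and the β-glucan library (orange), with 95% exact binomial intervals that cover counting error only. Erythroid-like cells took 2.64% and 4.68%, and T-like cells 46.9% and 41.1%.

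The series title names Th17 cells, T cells that make interleukin 17, so the second question is how type 3 genes differed in T-like cells. The interleukin 17 gene il17a/f1 (ENSSMAG00000005871) was higher in T-like cells of the β-glucan library, with 937 UMIs (299 CPM) against 378 UMIs (130 CPM) in the PBS library. Its log2 ratio was 1.19 (1.02 to 1.37). The cells that carried it held more of it, with a mean of 9.10 UMIs per positive cell against 3.35, and the highest cells held 167 and 61 UMIs. The top 1% of T-like cells of each library by il17a/f1 UMIs, 15 β-glucan and 23 PBS cells, held most of these UMIs. Without them 220 and 135 UMIs were left, and the log2 ratio was 0.58 (0.28 to 0.91). The share of T-like cells with a UMI was 7.06% against 5.12%, at median depths of 1740 and 1110.5 UMIs. With each cell thinned to 800 UMIs, which left out 129 and 517 shallower T-like cells, the shares were 5.12% and 4.38%, and the interval of their log2 ratio, -0.27 to 0.72, included 0. Most UMIs of the gene came from cluster 7, which has it among its top genes, with 909 of 937 UMIs in 166 β-glucan cells and 362 of 378 in 235 PBS cells. There 51.2% and 43.4% of cells had a UMI (interval of the log2 ratio -0.19 to 0.67), against 0.275% to 2.28% in clusters 1, 2 and 6. Among enterocyte-like cells, where the gene should be lacking, 5 of 1285 cells (0.389%, median 4486 UMIs) and 0 of 1487 (median 3976 UMIs, which allows a share of up to 0.202%) had a UMI.

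The other members of the type 3 list did not move together with il17a/f1. Of the 12 other measured members, 4 were higher and 8 lower in the β-glucan library. All 13, il17a/f1 included, had a median log2 ratio of -0.042 (-0.29 to 0.12), at percentile 34.0 of 10000 matched random lists. That median was 0.23 in thinned cells. The activator-protein factor batf had a log2 ratio of 0.70 (0.52 to 0.89) and il12rb2l, a receptor subunit, of 0.46 (0.22 to 0.72). The transcription factor genes irf4b and irf4a were lower, at -0.44 (-0.64 to -0.24) and -0.42 (-0.77 to -0.080), as was vdrb, a vitamin D receptor gene, at -1.21 (-2.09 to -0.59). The gene rorc, whose mammalian relative directs Th17 cells, was at -0.44 (-0.88 to -0.034), but at 0.045 in thinned cells and at 0.14 with the mean over cells. The intervals of stat3, hif1aa, rorcb, il12rb2, tgfb1a and MAF included 0, with log2 ratios of 0.21, -0.021, -0.30, 0.079, -0.042 and -0.33.

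The share of T-like cells with a UMI of any il17, il22, il21, il26 or rorc gene was 18.2% (16.3 to 20.3) in the β-glucan and 14.6% (13.2 to 16.2) in the PBS library. This set was not specific to T-like cells, since it was seen in 39.8% and 27.7% of the deeper enterocyte-like cells and in 13.3% and 11.1% of B-like cells (median 1511.5 and 1055 UMIs). After thinning, the shares were 12.1% and 10.5% in T-like, 8.69% and 4.35% in enterocyte-like, and 12.5% (6 of 48 cells) and 3.77% (2 of 53) in B-like cells. Within the T-like class the thinned shares were 49.4% and 46.3% in cluster 7 and 3.49% to 9.11% in clusters 1, 2 and 6. The log2 ratio of the T-like shares was 0.32 (0.078 to 0.56), fell to -0.090 with the stricter cell filter, and had an interval of -0.11 to 0.53 after thinning.

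Beyond the type 3 list, the lists higher in T-like cells of the β-glucan library included regulatory T, inflammatory cytokines, and dissociation stress and heat shock. The regulatory T list had 5 of 8 members higher and a median log2 ratio of 0.32 (0.071 to 0.68), at percentile 99.7. Its members included foxp3b (ENSSMAG00000003417), related to the master factor of regulatory T cells, at 1.38 (1.06 to 1.77), and tnfrsf9a, a costimulatory receptor, at 0.95 (0.67 to 1.26). Among its lower members was tgfb1a, which is also in the type 3 list, at -0.042 (-0.50 to 0.42). After thinning, foxp3b was seen in 4.21% of T-like cells against 2.01%, and in 0 of 1208 and 1 of 1426 enterocyte-like cells. The makeup of the T-like class differed as well. Cluster 1, its largest, took 13.2% of all kept β-glucan and 19.3% of PBS cells (log2 ratio -0.55, -0.71 to -0.39). Cluster 21, with foxp3b among its top genes, held 46 cells of the β-glucan and 22 of the PBS library, and foxp3b was seen in 73.9% and 81.8% of them. In cluster 6 it was seen in 65 of 295 and 36 of 364 cells, and after thinning in 8.48% and 5.40%, where the interval of the log2 ratio, -0.30 to 1.64, included 0. Cluster 1 had it in 4.90% against 1.10% of cells (log2 ratio 2.16, 1.03 to 3.39). After thinning these were 2.43% and 0.817%, and the interval, -0.11 to 3.47, included 0. Of the inflammatory cytokine list 6 of 7 members were higher, with a median of 0.54 (0.42 to 0.67) at percentile 99.98. The members with the most UMIs were the NF-κB inhibitor genes nfkbiaa at 0.54 and nfkbiab at 0.46. Larger ratios came from few UMIs, with IL-1b at 1.115 (81 against 33 UMIs), mmp13b at 1.74 (47 against 11) and mmp9 at 0.97 (39 against 17). Genes typical of other clusters, chosen after their values were seen, were also higher in T-like cells: slc10a2 with 59 against 6 UMIs, mpx with 43 against 12, zgc:174917 with 157 against 55 and the pancreatic ela3l with 301 against 154. Whether RNA of other cells adds to the cytokine list was not tested. The dissociation stress and heat shock list had 19 of 26 members higher and a median of 0.28 (0.15 to 0.40), with nr4a1 at 0.47 and hsp90ab1 at 0.094, and hspa8 at -0.033. It holds genes that tissue handling can raise, and it moved in the same class as the regulatory and cytokine lists.

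These list medians depended on which cells and genes entered. Cluster 20, a T-like cluster with mki67 and mmp25b among its top 10 genes, held 49 PBS and 44 β-glucan cells. Their median UMIs were 859 and 5159, so its β-glucan cells tended to weigh more in the sums. What it adds to the cytokine and cell cycle medians was not tested. The regulatory median was 0.0005 over genes with at least 100 UMIs, 0.78 in thinned cells and 0.86 with the stricter cell filter. The cytokine median was 0.18 to 0.27, below its interval, in other clusterings, from single-cell classes, over every deposited barcode and without doublet removal. The stress median went down to 0.11 without doublet removal. The cell cycle list had a median of 0.43 (0.16 to 0.61), with 17 of 23 members higher, but it was -0.35 with the stricter filter and turned in 6 further settings. The oxidative phosphorylation list was at 0.086 (0.039 to 0.16), percentile 97.9, and turned to -0.095 with the stricter filter. The other T-like lists lay between percentiles 3.07 and 96.5. Median-of-ratios scaling moved the median of all genes in T-like cells by 0.11.

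By the rule for named genes, the T-like genes highest in the β-glucan library were syt1a, lima1a, ELOVL7, TNFRSF11B, CD83, dlgap5, foxp3b, il17a/f1, dab2 and mmp13b. CD83, an activation marker of lymphocytes and dendritic cells, had 979 against 356 UMIs and a log2 ratio of 1.34 (1.17 to 1.53). The gene syt1a had 87 UMIs in 66 cells against 1 UMI in the PBS library. The genes lima1a, TNFRSF11B, dab2 and mmp13b rested on few cells, with 131 UMIs in 13 cells, 45 UMIs in 8 cells, 35 UMIs in 8 cells and 47 UMIs in 3 cells of the β-glucan library. In thinned cells TNFRSF11B, dab2 and dlgap5 turned, to -0.051, -0.051 and -0.35. The lowest were cry5, arpc5b, nadka, cdca7a, c6ast1, ssuh2rs1, trim37, scamp3, atp8a1 and EIF6, with log2 ratios from -2.17 (cry5) to -1.22 (EIF6).

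**Figure D2:**
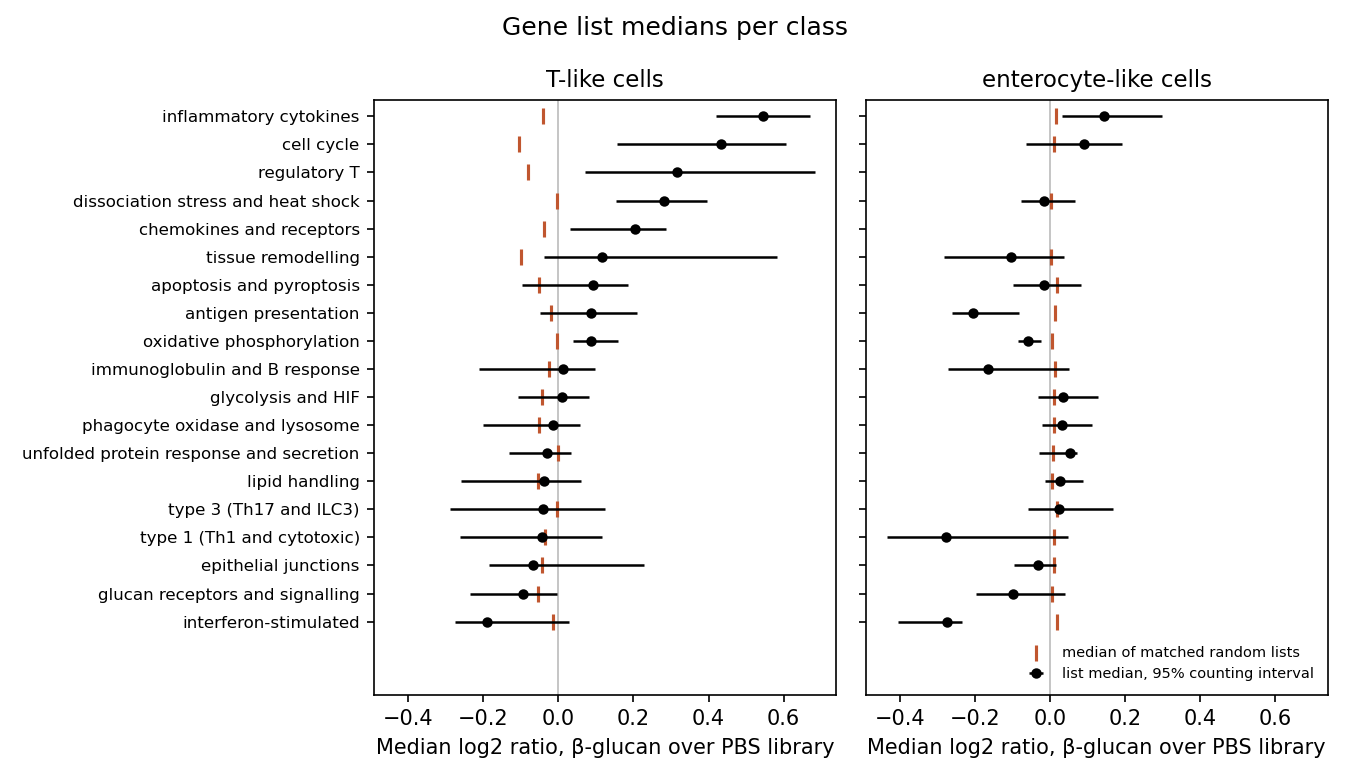
Median log2 ratio of each gene list, β-glucan over PBS library, in T-like cells (left) and enterocyte-like cells (right). Black points are list medians with 95% Poisson redraw intervals, which cover counting error only, and orange ticks are the medians of matched random lists. The interferon-stimulated median was -0.27 in enterocyte-like cells and -0.19 in T-like cells.

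The third comparison concerns the enterocyte-like cells. Interferon-stimulated genes, induced in antiviral and inflammatory responses, were lower in the β-glucan library, with 15 of 17 measured members lower and a median log2 ratio of -0.27 (-0.40 to -0.24), below all 10000 random lists. The ubiquitin-like gene isg15 was at -0.90 (-1.001 to -0.806), the transcription factor gene stat1a at -0.49 (-0.63 to -0.36) and the proteasome subunit gene psmb8a at -0.26 (-0.38 to -0.16). Antigen presentation genes had 14 of 22 members lower and a median of -0.20 (-0.26 to -0.082), though cd74a, the class II invariant chain, was higher at 0.68 (0.62 to 0.74). The 2 lists share NLRC5, psmb8a, psmb9a, tap1 and tap2a, so they are not separate observations. In cells thinned to 800 UMIs the interferon median was -0.013 and the antigen presentation median turned to 0.017, while isg15 was still at -0.61 (-0.94 to -0.29). The interferon median was -0.16 with the mean over cells.

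The enterocyte-like genes highest in the β-glucan library were grin2da, zgc:174917, s100a1, mpx and col4a6. Of the 128 s100a1 UMIs of the β-glucan library 73 came from 1 cell. The peroxidase gene mpx (ENSSMAG00000020424) had 4563 against 703 UMIs, a log2 ratio of 2.58 (2.49 to 2.72), and irg1l, an immune response gene, was at 1.33 (1.18 to 1.56). Of these mpx UMIs 3837 came from cluster 14, which drew 96.8% of its cells from the β-glucan library and so may be a feature of that library. Of the irg1l UMIs 704 of 903 came from it too, and irg1l was at -0.22 (-0.53 to 0.070) in cluster 3 and at -0.72 (-1.58 to -0.21) in cluster 5. The gene zgc:174917 is also among the top 10 genes of cluster 14. In cluster 5, which held similar cell numbers of both libraries, mpx was at -0.29 (-0.50 to -0.092). The share of cells with an mpx UMI was higher in cluster 3, at 20.2% against 12.1% (8.70% and 4.02% after thinning, log2 ratio 1.11, 0.25 to 2.01), and in T-like cells, at 2.61% against 0.363%. After thinning it was 3.95% against 6.19% in cluster 4 (interval -1.74 to 0.37) and 16 of 348 against 17 of 350 cells in cluster 5 (-1.16 to 0.99). The lowest were cyyr1, sez6a, meig1, st6galnac5a and apoa2. Most of the apoa2 UMIs of the PBS library, 78 of 83, came from 1 cell. The chitinase gene chia.1 was at -1.41 (-1.56 to -1.30), and the bile acid genes slc10a2, an ileal transporter, and fabp6, a carrier, had 5035 against 1096 and 1428 against 425 UMIs; these 3 were chosen after their values were seen.

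Over the sum of all kept cells, which mixes cell makeup with expression, the lists with the lowest medians were complement at -0.36 (6 of 6 members lower), inflammatory cytokines at -0.35 (8 of 13), interferon-stimulated genes at -0.30 (15 of 17), tissue remodelling at -0.24 (10 of 17) and antigen presentation at -0.22 (18 of 24). The cytokine list was instead higher within T-like cells, at 0.54 over 7 members. In enterocyte-like cells it was at 0.145 over 8 members, but at -0.018 with the stricter cell filter. Over all cells, its member il12bb, a subunit of interleukin 12, was at -1.31, IL-1b at -0.55 and il11a at -0.59, while irg1l was at 1.24. The glucan receptor and signalling list, with 21 of 27 members lower, had a median of -0.17 (-0.29 to -0.13), at percentile 1.98. Within classes it stood out less, at -0.094 (percentile 30.1) in T-like and -0.099 (percentile 7.84) in enterocyte-like cells. In tuft-like or ionocyte cells it was at 0.012 (percentile 67.8) and in cluster 8 at -0.071 (percentile 31.4). The cell cycle list was higher, at 0.11, and lipid handling at 0.070, which turned to -0.016 with the stricter cell filter. The interferon and antigen presentation medians turned to 0.028 and 0.11 in thinned cells. The highest genes by rule were grin2da, mpx, slc10a2, zgc:174917, col4a6, cyp7a1, msx1a, si:dkey-243k1.3, KNDC1 and TMEM236. The lowest were cyyr1, sez6a, si:dkey-266f7.9, ttc36, st6galnac5a, GCG, apoa2, zgc:101810, hmox1a and meig1. The gene cyp7a1, for the rate-limiting enzyme of bile acid synthesis, was at 2.00 (1.89 to 2.44), and GCG, which encodes proglucagon, at -1.82 (-1.96 to -1.74).

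Smaller classes were compared in the same way. In erythroid-like cells mt2, a metallothionein, was at 0.86 (0.72 to 0.99) and hbbe1.2, a haemoglobin chain with 2806 CPM in the β-glucan library, at 0.81 (0.61 to 1.00), while hbbe2, a far more abundant haemoglobin chain chosen after its values were seen, was at -0.063 (-0.085 to -0.041) with 140306 CPM. The genes hnrnpr, pnp5a and desi1a were also high, and vps29, si:ch1073-314i13.4, ppdpfb, cdc37 and ube2d3 were low. Their stress list was at -0.25 (-0.44 to -0.055), with 8 of 11 members lower. Of 10 measured mitochondrial genes, chosen after their values were seen, 9 were lower in the same cells, among them MT_COX3 at -0.92 (-1.11 to -0.72) and MT_COX2 at -0.74 (-0.92 to -0.55). The tuft-like or ionocyte class is cluster 10, named from best4, cftr and otop2, none of which was among its top 10 genes. The other listed markers of the class, pou2f3, trpm5, avil and foxi1, were not among its raised markers. The class name is therefore a label from the marker list and does not identify tuft cells. The tuft cell gene avil was among the top 10 genes of the unnamed cluster 15. In tuft-like or ionocyte cells the junction list had 19 of 20 members lower and a median of -0.43 (-0.59 to -0.34), with epcam at -0.41, but it was 0.040 over every deposited barcode. Lipid handling and oxidative phosphorylation were higher there, at 0.67 and 0.42, but turned to -0.031 and -0.22 in thinned cells. The named genes of this class were fabp2, gstr, alas1, chia.1 and rbp2a, which were higher, and pard6b, lipg, gldc, glcci1a and mindy1, which were lower. Single cells gave 57 of the 58 chia.1, 352 of the 1235 alas1 and 149 of the 570 gstr UMIs of the β-glucan library, and fabp2 and rbp2a were also among the top 10 genes of cluster 11, an enterocyte-like cluster. In cluster 8 the highest were eno1a, fosb, vamp2, ufm1 and trbc2 and the lowest ccn2a, fermt3b, fam32a, hsp90aa1.2 and arhgap27l, with ccn2a at -1.75 from 25 and 17 UMIs but at 3.39 in thinned cells. There the oxidative phosphorylation list was at 0.34 (0.11 to 0.56). Scaling moved the median of all genes by 0.24 (TMM) and 0.21 (median of ratios) in cluster 8, by 0.13 (median of ratios) in tuft-like or ionocyte cells and by 0.11 (TMM) in erythroid-like cells.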

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

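Signals outside the comparisons were noted where they passed 3 counts. Barcodes left out by the cell filter held 4 il17a/f1 UMIs in the β-glucan library and 2 in the PBS library. Features without a symbol, which entered no list, took 18.0% of the UMIs of kept cells in the PBS library and 18.4% in the β-glucan library.

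The tests in the next paragraphs were set before their results were seen, except that of the share of the il17a/f1 cluster and those of equal cluster weights, scaling and deep cells in the third pattern.

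The first pattern is the higher il17a/f1 in T-like cells of the β-glucan library. Thinning left the log2 ratio at 1.25 (0.99 to 1.53), but it cannot decide on greater depth per cell. CPM is already divided by total UMIs, and thinning keeps each gene's expected share of a cell's UMIs. The share of positive cells, which does depend on depth, had a log2 ratio of 0.22 (-0.27 to 0.72) after thinning. A few extreme cells held most of the UMIs, and without the top 1% of T-like cells the ratio was lower, at 0.58 (0.28 to 0.91). That interval takes UMIs of the same cell as independent. The cut took 23 of the 113 positive PBS cells but 15 of the 103 positive β-glucan cells, an unequal part of each upper tail. It therefore cannot decide whether cells with many UMIs carry the ratio. More cells of the cluster richest in il17a/f1, found without that gene in the clustering, are argued against as the whole source by a log2 ratio of its share of T-like cells of 0.075 (-0.22 to 0.37). Free RNA is argued against by the level in enterocyte-like relative to T-like cells of the β-glucan library, -8.73 (-9.80 to -7.85) on the log2 scale. An effect of β-glucan may underlie the pattern, but with 1 library per treatment it cannot be told apart from a difference between fish or libraries.

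The second pattern is the higher mpx and irg1l in enterocyte-like cells of the β-glucan library. The other neutrophil markers measured there (cybb, tcn2, IL-1b, mmp9 and mmp25b) did not rise with mpx as a set. Their median log2 ratio was 0.18 (-0.072 to 0.34) against 2.58 for mpx. However, IL-1b and mmp9 were also seen in macrophage-like cells, and the markers were not tested in cluster 14 alone. Neutrophil RNA or neutrophils sharing droplets are therefore not excluded. A greater number of enterocytes of the slc10a2 kind also stays open. In cells without an slc10a2 UMI mpx was at 3.28 (3.16 to 3.46), but only 44.2% of the β-glucan cells of cluster 14, the source of most mpx UMIs, had a UMI of slc10a2, so cells without one can be of that kind. The treatment remains possible but untested, since 1 library per treatment cannot be told apart from 1 group of fish, and most of the UMIs came from a cluster found almost wholly in that library.

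The third pattern is the lower interferon-stimulated list in enterocyte-like cells of the β-glucan library. The scaling is argued against, since it would lower matched random lists as much, and the list median lay at -0.29 (-0.42 to -0.25) relative to theirs. The mix of the 4 clusters with at least 50 cells in both libraries is argued against as the whole source, since giving each the same weight in both libraries left the median at -0.34 (-0.46 to -0.26). Clusters 3, 4 and 5 had medians of -0.27, -0.41 and -0.36 with intervals below 0. An upper bound below 0 in every cluster, the test set beforehand, was not met in cluster 11, at 0.099 (-0.33 to 0.45) over 7 members. Deep cells weighing more in the sums could account for part or all of the lower list median. The mean over cells gave -0.16 with an interval that included 0 (-0.23 to 0.040, cells redrawn). Thinning, which also leaves out shallow cells and most UMIs, gave -0.017 (-0.22 to 0.22) over the same 17 members, although isg15 stayed lower. An effect of β-glucan cannot be told apart from other differences with 1 library per treatment.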

How the results depend on the processing

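With 1 library per group, leaving out a replicate was not possible. No paired analysis was possible because each group has 1 library and the labels link no fish between them. The T-like il17a/f1 ratio kept its direction in every setting tried, between 0.58 without the top 1% of T-like cells by its UMIs and 1.30 under median-of-ratios scaling, with 0.91 under the stricter cell filter. The alternatives without the cluster genes il17a/f1, foxp3b, mpx and irg1l, with cluster 8 counted as T-like, with other-gene symbols kept, with il17a/f1 alone, and il17a/f1 under other cell sets were chosen after seeing the data. Of 1057 list medians under an alternative, 840 stayed within the counting interval of the value reported, and 177 left it without a called change of sign. A change of sign was called only where the reported interval excluded 0, which holds for 413 of them, and 40 of these 413 changed sign. Of 703 named gene ratios 512 stayed and 185 left, and 6 of 655 changed sign. These counts include the minimums of 10 and 100 UMIs, which cannot change the ratio of a single gene. Under them 75 and 44 ratios counted as having stayed. Another 17 and 7 counted as having left only because the reported ratio, with its pseudocount, lies outside its interval without one. Where a setting's construction does not show the cause, the cause was not tested. All values here are log2 ratios, or their list medians, β-glucan over PBS, and depth limits the T-like values, at a median of 1110.5 UMIs in PBS cells.

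With at least 500 genes and at most 10% mitochondrial UMIs, which kept fewer and other cells, the share ratios were 0.21 for T-like, -0.18 for enterocyte-like, -1.12 for enteroendocrine-like, 1.83 for erythroid-like and -0.80 for goblet-like cells, and the ratio of T-like cells with type 3 UMIs was -0.090. T-like medians were 0.86 for regulatory T, -0.095 for oxidative phosphorylation and -0.35 for cell cycle. Lipid handling was -0.016 over all cells and inflammatory cytokines -0.018 in enterocyte-like cells. With classes from single cells, share ratios were 0.097 for T-like, 0.070 for enterocyte-like and 0.41 for goblet-like cells, and T-like medians were 1.00 for regulatory T, 0.25 for inflammatory cytokines, -0.090 for oxidative phosphorylation and -0.35 for cell cycle. Among immune-like cells alone, nearly all of them T-like, the T-like share ratio was 0.0024 and could hardly differ from 0.

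With cells thinned to 800 UMIs, medians over all cells were 0.028 for interferon-stimulated, 0.11 for antigen presentation, 0.020 for glycolysis and HIF, 0.059 for oxidative phosphorylation, 0.057 for the unfolded protein response and 0.16 for apoptosis and pyroptosis. T-like medians were 0.23 for type 3, 0.78 for regulatory T and 0.035 for cell cycle, with TNFRSF11B at -0.051, dlgap5 at -0.35, dab2 at -0.051 and rorc at 0.045. Enterocyte-like medians were -0.013 for interferon-stimulated, 0.017 for antigen presentation and 0.0049 for oxidative phosphorylation. In tuft-like or ionocyte cells oxidative phosphorylation was -0.22 and lipid handling -0.031, and ccn2a in cluster 8 was 3.39. With the mean over cells, medians over all cells were 0.014 for epithelial junctions, 0.030 for interferon-stimulated, 0.13 for antigen presentation and 0.058 for oxidative phosphorylation. In that setting cell cycle was 0.087 and rorc 0.14 in T-like cells, interferon-stimulated -0.16 and oxidative phosphorylation 0.016 in enterocyte-like cells, and glycolysis and HIF 0.16 in tuft-like or ionocyte cells.

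Under TMM scaling, medians over all cells were 0.018 for phagocyte oxidase and lysosome, 0.0009 for glycolysis and HIF, 0.050 for oxidative phosphorylation and 0.022 for the unfolded protein response. Under median of ratios phagocyte oxidase and lysosome was 0.0072, oxidative phosphorylation 0.039 and the unfolded protein response 0.011. With at least 10 UMIs T-like inflammatory cytokines were 0.76, and with at least 100 UMIs regulatory T was 0.0005 and cell cycle 0.12.

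Over every deposited barcode, T-like inflammatory cytokines were 0.26 and cell cycle 0.064, enterocyte-like inflammatory cytokines -0.17 and oxidative phosphorylation 0.17. In tuft-like or ionocyte cells junctions were then 0.040, glycolysis and HIF 0.0006, oxidative phosphorylation -0.035 and lipid handling -0.74. In T-like cells without doublet removal, inflammatory cytokines were 0.18, stress 0.11 and cell cycle -0.056. Inflammatory cytokines and cell cycle were 0.27 and -0.023 at resolution 0.5, 0.26 and -0.0028 at resolution 2.0, 0.21 and -0.077 with ComBat, and 0.26 and -0.016 when clustered without the cluster genes. The stress median was 0.15 at resolution 2.0 and 0.14 without those genes.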

Other observations

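The genes in these paragraphs were chosen after their values were seen, and macrophage-like and enteroendocrine-like cells lacked the 100 cells in both libraries set for the comparisons. Macrophage-like cells, 106 in the PBS and 55 in the β-glucan library, carried more of the coagulation factor gene f13a1b in the β-glucan library, at 43051 against 8796 CPM, more of the matrix protease gene mmp9, at 500 against 92.0 CPM, and less IL-1b, at 344 against 742 CPM. The class joins cluster 16 (74 and 46 cells), with f13a1b among its top 10 genes, and cluster 22 (32 and 9 cells), without it, so their mix differed between the libraries. Their complement genes C1QA, C1QB and C1QC had log2 ratios of 0.47, 0.47 and 0.39, although all 3 were lower over the sum of all cells. In enteroendocrine-like cells (72 and 39), the proglucagon gene GCG had 894 against 3399 CPM, whereas the peptide gene pyyb had 22521 against 16507 CPM.

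Cluster 18 was led by genes of pancreatic digestive enzymes, cpa1, ela3l and CEL, and held 55 cells of the PBS and 40 of the β-glucan library. Several genes were close to absent in 1 library: grin2da had 5 and 72 UMIs over all cells in the PBS and β-glucan library, syt1a 1 and 87 in T-like cells, and cyyr1 135 and 6 and sez6a 36 and 1 over all cells. No explanation of these was tested.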
